A study of Mus musculus with 36 samples.

How the data were processed

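Expression of a custom panel of 224 TaqMan assays was measured by real-time PCR on OpenArray cards in 36 samples of mouse ileal mucosa, the lining of the last part of the small intestine. Per the labels' protocols, total RNA was isolated with the mirVana kit, had an average RNA integrity number over 9, and was carried as cDNA onto cards cycled in an OpenArray NT instrument. The deposited table holds raw Ct values, per the file headers, with no normalization by the authors, and its opening line calls it a truncated example of raw Ct data. Ct is the PCR cycle at which the fluorescence of a well crosses a threshold, so a lower Ct stands for more template, and each cycle corresponds to 1 doubling if amplification is complete. The amplification efficiency and the threshold setting are not given in the sources used here. A value of 40 marked a well without amplification and was treated as missing. There were 291 such wells among 8064, or 3.61%, and the measured values lay between 11.6 and 32.4.

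Each column was matched to its sample by its title. The groups came from the labels for colonisation, with 9 samples in each of germfree, E. coli CEC, E. coli Nissle and conventional. The series' design text speaks of RNA from the mice being pooled, while the sample titles carry individual numbers, so whether a sample is a single mouse or a pool is open. The p-values therefore measure the spread between these samples, which may be partly technical. No pair of samples held an identical Ct for any assay, and the lowest SD of log2 differences between samples of 1 group was 0.42, so all samples were kept apart.

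The assays carry only catalogue IDs in the deposited table. The gene table at hand pairs locus tags and RefSeq accessions with symbols, and 0 of the 224 IDs were found in it. The files do not pair the IDs with genes, so no gene is named, and the 23 gene lists fixed for this tissue could not be tested. For the same reason the planned scaling to reference genes gave way to its written fallback, the mean Ct of the 146 assays measured in all 36 samples. The log2 relative level is minus the difference between an assay's Ct and that mean, so a higher value stands for more transcript relative to the panel. It is a relative measure: a shift shared by most assays of the panel is removed by it.

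Assays measured in at least 5 of 9 samples of every group were tested, which left 216. The other 8 included 2 that did not amplify in any sample. limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with default settings) was fitted to all 36 samples with 1 term per group, and p-values were adjusted by Benjamini-Hochberg over the assays of a comparison, two-sided, with a threshold of 0.05. The 5 comparisons were each E. coli strain with germfree, conventional with germfree, Nissle with CEC, and conventional with the mean of the mono-associated groups. The mean of the mono-associated groups against germfree was added after seeing the data, from the same fit. The simulated overlap of call lists, the test of spread and the screen for outlying values were not in the plan written before the data were examined. That plan held the tests of level, detection and similarity. It also held the alternatives and the rule for naming, except where the text says that a choice followed. That rule took up to 12 assays each way by log2 fold change among those past the threshold; without gene names it was shortened to 2 higher and 2 lower per comparison. Assays left out were compared for detection by Fisher's exact test.

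The number of assays measured per sample stands in for depth. It ran from 214 to 222, apart from 198 in CEC replicate 6 and 175 in Nissle replicate 6. The median 95% confidence interval of a log2 fold change reached 0.52 either side for Nissle against CEC and 0.50 for conventional against germfree. The limma step was tested on simulated data for conventional against germfree with 216 assays, of which 60 were changed. Over 20 simulations it recovered 41% of changes of 0.5 log2 units, 77.8% of changes of 1 and 95.5% of changes of 2, and 3.53% of the calls were false. The simulated values were independent between assays and held no outlying sample, so these rates may not hold for the measured data.

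Alternatives covered quantile normalization, raw Ct, filled-in undetermined wells, Ct above 28 treated as missing, other filters on missing values, fits on the compared groups alone, eBayes with trend and robust settings, sample quality weights, a permutation test per assay, the replicate number as a block and each sample left out in turn. Scaling to the median of the 146 assays or to the 20 steadiest of them, and leaving out CEC replicate 7 with Nissle replicate 6, were chosen after seeing the data. That last repeat scaled each sample to the 179 assays measured in all samples left, and was run again with the original 146. Chance overlap from shared germfree samples was simulated with 100 regroupings of the residuals, using lists of the observed lengths. Permutation and exact tests used NumPy and SciPy in Python, and plots were drawn with matplotlib.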

Results

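The series measured transcripts in the ileal mucosa of mice that differed in their gut bacteria. Germfree mice, which carry no microbes, were the control. The other groups were mono-associated with E. coli CEC (an abbreviation the labels do not expand), mono-associated with E. coli Nissle (a strain used as a probiotic), or conventional, which carry an ordinary complex microbiota. The labels of the mono-associated samples give the number 21 for colonisation, without a unit. Each group held 9 samples. The mean Ct of the 146 assays measured in every sample was 21.3 ± 0.13 (SD, n = 9) in germfree, 21.3 ± 0.252 in CEC, 21.3 ± 0.171 in Nissle and 21.2 ± 0.103 in conventional samples.

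A sample typically gave a Ct for 216 to 219 of the 224 assays, the range of the group medians. Exceptions were CEC replicate 6, with 198 assays, and Nissle replicate 6, with 175. CEC replicate 7 was measured for 217 assays, but its profile stood apart from its group: its median absolute deviation was 1.05 log2 units, and 32 assays lay more than 3 log2 units from the group's level. Counts of changed assays are therefore given with all samples and again without CEC replicate 7 and Nissle replicate 6, a repeat added after seeing the data.

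**Figure D1:**
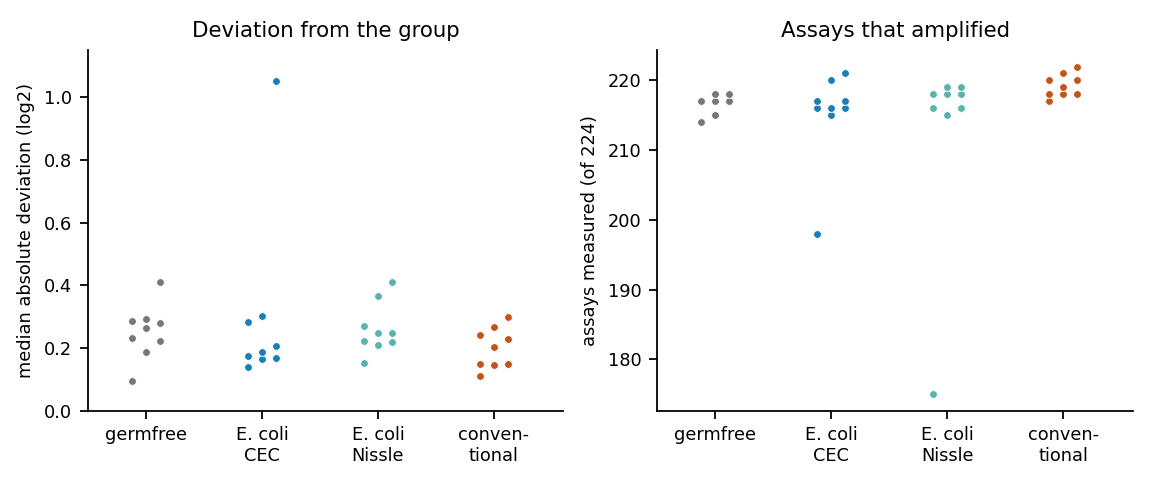
Each point is 1 of 36 samples, by group. Left, the median over assays of the absolute difference from the group's level, in log2 units, where CEC replicate 7 lies at 1.05. Right, the number of the 224 assays with a Ct, where CEC replicate 6 lies at 198 and Nissle replicate 6 at 175 (the right axis does not start at 0).

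In the main fit the most assays differed between mice with a complex microbiota and mice with none. With sample quality weights that count (94) was about equal to the one against the mono-associated mean (95). In conventional samples 56 of 216 assays differed from germfree, 26 higher and 30 lower, and 14 of the higher but 6 of the lower ones by more than a doubling. Assay Mm00470560_m1 rose by 4.11 ± 0.72 log2 units (SE; limma, adjusted p = 6.22e-05), a 17.3-fold change, from a log2 relative level of -2.70 ± 0.34 (SD, n = 9) in germfree to 1.41 ± 0.41 (SD, n = 9) in conventional samples. The SE comes from the spread within all 4 groups of the fit, and the SD of this assay was 2.20 in CEC and 2.19 in Nissle samples. Assay Mm00472168_m1 rose by 3.52 ± 0.32 (adjusted p = 3.5e-10), an 11.5-fold change. Both were higher in all 9 conventional samples than in any of the 9 germfree samples.

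Among the assays that fell, Mm01213380_s1 had a log2 fold change of -1.93 ± 0.56 (adjusted p = 0.00895) and was below the germfree mean in 8 of 9 conventional samples. Mm00489956_g1 had one of -1.92 ± 0.53 (adjusted p = 0.00655), with all 9 conventional samples below every germfree sample. Its SE was 0.20 without CEC replicate 7 and Nissle replicate 6. Most changes were smaller than these. The median log2 fold change was 1.05 among the 26 assays that rose and -0.50 among the 30 that fell. With only the 2 compared groups fitted, 82 assays were called, 37 higher and 45 lower. The permutation test per assay also called 82, 35 higher and 47 lower.

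Without CEC replicate 7 and Nissle replicate 6, neither of which belongs to these groups, 90 of 215 assays were called, 32 higher and 58 lower, and 55 of the 56 calls were among them. That repeat changed both the estimate of spread and the scaling, which then used the 179 assays measured in the remaining samples. Scaled to the original 146 assays, it called 73, 30 higher and 43 lower. Of its 90 calls only 50 were made under all 5 scalings, 29 higher and 21 lower. With all samples, too, the balance of higher and lower calls depended on the scaling. With the median of the 146 assays it was 28 higher and 15 lower, with the 20 steadiest assays 32 and 13, and with raw Ct 28 and 14, while 36 assays (24 higher, 12 lower) were called in the same direction under all 5 scalings.

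Colonisation by a single E. coli strain changed fewer of the assays. With CEC, 11 assays differed from germfree, 6 higher and 5 lower. Mm00470560_m1 rose by 2.79 ± 0.72 log2 units (SE; limma, adjusted p = 0.0187) and was above the germfree mean in 9 of 9 CEC samples. The CEC samples lay in 2 sets, with CEC replicates 6, 8, 9 and 10 at log2 relative levels of 1.40 to 3.22 and the other 5 at -2.23 to -1.36, above the germfree mean of -2.70 by far less. Mm00487425_m1 rose by 1.06 ± 0.31 (adjusted p = 0.0378), higher than the germfree mean in 7 of the 8 CEC samples with a value. Mm01962902_s1 fell, with a log2 fold change of -1.60 ± 0.41 (adjusted p = 0.0187, 8 of 9 samples), as did Mm01611157_gH, at -0.61 ± 0.15 (adjusted p = 0.0184, 9 of 9 samples).

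The count for CEC rested on single samples. It was 56 without CEC replicate 7, 65 (24 higher, 41 lower) without that sample and Nissle replicate 6, 2 without CEC replicate 9, 7 without germfree replicate 10 and 6 without germfree replicate 22 or 31. Without CEC replicate 9 all 4 named assays missed the threshold, Mm00470560_m1 with a limma adjusted p of 0.0508. Mm00487425_m1 missed it without any 1 of 11 samples, and in the permutation test per assay Mm00487425_m1 (adjusted p = 0.110) and Mm01962902_s1 (adjusted p = 0.0697) did, as they did with only the 2 groups fitted (limma, adjusted p = 0.118 and 0.0723). With undetermined wells filled in Mm00487425_m1 fell to 0.71 (adjusted p = 0.314). Its only undetermined CEC well, in CEC replicate 6, was filled at 1 cycle above the assay's highest Ct. The other CEC samples lay between Ct 17.8 and 20.2, so that value depends on how 1 well was filled. Scaled to the 20 steadiest assays the split was 11 higher and 5 lower, and under quantile normalization 27 assays were called, 13 higher and 14 lower. Under all 5 scalings 9 assays were called, 5 higher and 4 lower. With CEC replicate 7 and Nissle replicate 6 left out, only 31 of the 65 calls were made under all 5 scalings, 22 higher and 9 lower, and scaled to the original 146 assays the split was 29 higher and 28 lower.

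With Nissle, 16 assays differed from germfree, 8 higher and 8 lower. Mm00470560_m1 rose by 2.96 ± 0.72 log2 units (SE; limma, adjusted p = 0.0148) and was above the germfree mean in 9 of 9 Nissle samples, but unevenly. Nissle replicate 7, at a log2 relative level of -2.65, lay within the germfree range of -3.18 to -2.13, while replicate 2 reached 3.84. Mm01208559_m1 rose by 2.02 ± 0.55 (adjusted p = 0.0255, 8 of 8 samples with a value). Mm00467543_m1 fell, with a log2 fold change of -1.23 ± 0.35 (adjusted p = 0.0255, 9 of 9 samples). Its log2 fold change was -0.71 under quantile normalization (limma, adjusted p = 0.220) and -0.65 with Ct above 28 treated as missing (adjusted p = 0.182), and its call was also lost with only the 2 groups fitted (adjusted p = 0.0514), in the permutation test (adjusted p = 0.0542) and without any 1 of 5 samples. Mm01288989_m1 fell as well, at -1.10 ± 0.29 (adjusted p = 0.0255), but was measured in only 5 Nissle and 6 germfree samples at a Ct of about 30.1 in germfree, and under quantile normalization its log2 fold change was 0.0323. That call was also lost with undetermined wells filled in (-0.85, limma adjusted p = 0.454), with the trend and robust eBayes settings (adjusted p = 0.0744) and in the permutation test (adjusted p = 0.0601).

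Without CEC replicate 7 and Nissle replicate 6 the count for Nissle was 36 (16 higher, 20 lower), with CEC replicate 7 alone left out it was 35, and without germfree replicate 31 it was 6. Leaving out Nissle replicate 1 or 4 gave 9, and replicate 2 or 3 gave 10. With raw Ct Mm01208559_m1, Mm00467543_m1 and Mm01288989_m1 narrowly missed the threshold (limma, adjusted p = 0.0502) at little changed log2 fold changes of 2.04, -1.21 and -1.03, and all 3 missed it without germfree replicate 31 (adjusted p = 0.0598). With undetermined wells filled in the log2 fold change of Mm01208559_m1 itself fell to 1.28 (adjusted p = 0.343). Its only undetermined well, in Nissle replicate 6, was filled at 1 cycle above the assay's highest Ct. The other Nissle samples lay between Ct 22.7 and 24.1, so that value depends on how 1 well was filled. The split was 4 higher and 9 lower with the median scaling, 4 and 6 under quantile normalization and 1 and 4 with raw Ct. Under all 5 scalings 5 assays were called. With CEC replicate 7 and Nissle replicate 6 left out, 17 of the 36 calls were made under all 5, 8 higher and 9 lower, and scaled to the original 146 assays the split was 21 higher and 16 lower.

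**Figure D2:**
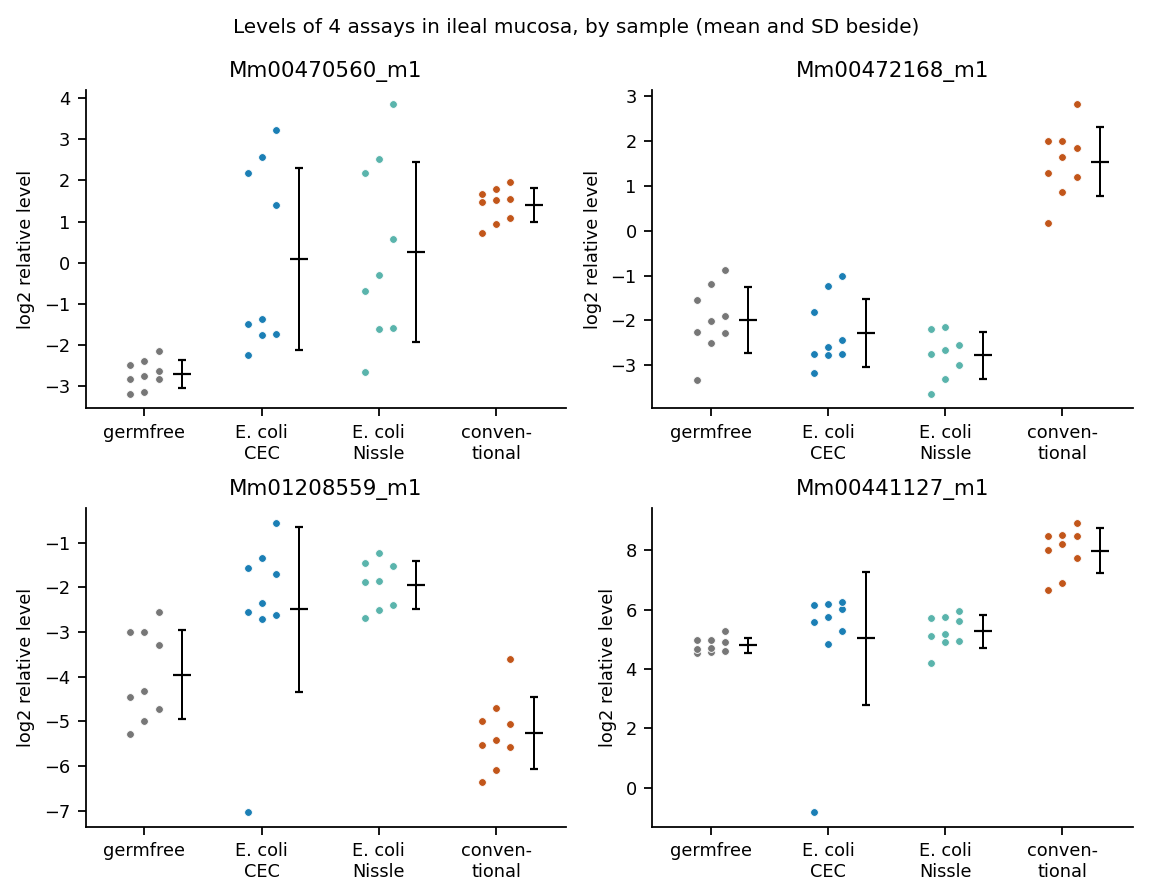
Log2 relative level (vertical axis, log2 units) of 4 assays in each sample, by group, with the mean and SD drawn beside the points. Mm00470560_m1 was low in germfree and high in conventional samples, and in the mono-associated groups it ranged from -2.65 to 3.84. Mm00472168_m1 and Mm00441127_m1 stood highest in conventional samples, and Mm01208559_m1 had its lowest mean there, with CEC replicate 7 as the lowest single sample.

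The comparison of Nissle with CEC addressed whether the strains acted differently on the mucosa. Of 216 assays, 1 differed, and 12 had an unadjusted p under 0.05, against 10.8 expected by chance. That assay was Mm01288989_m1, lower with Nissle, with a log2 fold change of -1.78 ± 0.31 (limma, adjusted p = 0.00183). It was measured in 5 samples of each group, at a mean Ct of 29.4 with CEC and 31.1 with Nissle. The call was lost under quantile normalization (log2 fold change -1.27, limma adjusted p = 0.696) and with undetermined wells filled in (-0.95, adjusted p = 0.616). It was also lost with the replicate number as a block (-1.58, limma adjusted p = 0.405). The permutation test could not judge it: with 5 samples a side the smallest exact p is 0.00794, which Mm01288989_m1 reached and which cannot pass alone among 216 assays. It was also lost without any 1 of the 10 samples in which it was measured, since the assay then had too few values to be tested, and without Nissle replicate 4 the count was 2.

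For 149 of the 216 assays the 95% confidence interval of the Nissle against CEC difference lay within 1 log2 unit either side of 0, so larger differences remain possible in the others. Without CEC replicate 7 and Nissle replicate 6 limma called 0 of 215 assays, with 14 at an unadjusted p under 0.05, and 180 intervals lay within that range. Mm01288989_m1 was not tested there, since CEC replicate 7 was 1 of its 5 CEC samples.

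The responses to the strains were correlated across the 146 assays measured in all samples. These hold fewer of the first 112 assays in the table's order, where 47 were undetermined in Nissle replicate 6 and 25 in CEC replicate 6. Whether a shift shared by part of the panel contributed to the correlation was not tested. Their log2 fold changes against germfree had a Pearson r of 0.79 and a Spearman rho of 0.684 across assays, which are not independent replicates. Both comparisons use the same germfree samples, which alone gave a mean r of 0.51, and at most 0.887, in simulations of unchanged groups. With the germfree samples split so that each strain had its own controls, r averaged 0.645 over 100 splits (range 0.514 to 0.774). The covariance of the fold changes was 0.218, against a mean of 0.0529 and at most 0.144 from the shared controls alone. Without CEC replicate 7 and Nissle replicate 6, over the 179 assays then measured in all samples, it was 0.29, with an r of 0.874. Shared controls alone then gave a mean covariance of 0.0298 and at most 0.101.

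Of the calls, 2 assays were higher and 3 lower with both strains, and 0 were called in opposite directions. Independent lists would share 0.222 and 0.185. Lists of the same lengths from simulated unchanged groups with shared germfree samples shared a mean of 1.59 and 1.10. At least as many were shared in 50 and 10 of 100 simulations, so the counts alone did not show an overlap beyond chance. In the simulations every group was unchanged and the lists were held to the observed lengths. They cannot tell how much overlap assays that truly changed would share by chance. With those 2 samples (CEC replicate 7, Nissle replicate 6) left out, the strains shared 13 higher and 15 lower calls (1.79 and 3.81 for independent lists), again with 0 in opposite directions. Shared controls alone then gave a mean of 5.62 and 9.87, and at least as many in 1 and 11 of 100 simulations, so only the overlap of higher calls was rare there. All 5 of the shared calls with all samples were also called in conventional mice in the same direction, Mm00470560_m1 among the 2 higher and Mm01611157_gH among the 3 lower ones. Shared germfree samples alone gave at least as many in 27 and 6 of 100 simulations. With the 2 samples left out, 6 higher and 10 lower calls were common to all 3 comparisons, and 18 and 18 of 100 simulations gave at least as many. Neither count was therefore shown to be beyond chance. For Mm01611157_gH the log2 fold changes against germfree were -0.61 with CEC, -0.64 with Nissle and -0.76 in conventional samples.

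The last comparison set mice with a complex microbiota against mice with a single strain. The labels give a number for colonisation, without a unit, only for the mono-associated samples. Any difference between these groups in the length of colonisation or in rearing can therefore not be told apart from microbial complexity. Between conventional samples and the mean of the mono-associated groups 46 assays differed, 19 higher and 27 lower in conventional samples. Mm00472168_m1 was higher by 4.06 ± 0.28 log2 units (SE; limma, adjusted p = 1.73e-13), a 16.7-fold change, and Mm00441127_m1 by 2.85 ± 0.48 (adjusted p = 3.7e-05). In both, all 9 conventional samples exceeded every mono-associated sample. Neither assay passed the test between the mono-associated mean and germfree, where the log2 fold changes were -0.54 (95% confidence interval -1.11 to 0.04) and 0.34 (-0.64 to 1.33). Both passed it without CEC replicate 7 and Nissle replicate 6, at -0.68 (limma, adjusted p = 0.0410) and 0.67 (adjusted p = 0.0256).

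Lower in conventional samples were Mm01208559_m1, at -3.05 ± 0.47 (adjusted p = 8.07e-06), and Mm00452283_m1, at -1.80 ± 0.46 (adjusted p = 0.00492), each below the mono-associated mean in 9 of 9 conventional samples. CEC replicate 7 lay far below its group in both, and without it and Nissle replicate 6 the log2 fold changes were -3.32 and -2.22. Mm01208559_m1 was higher in the mono-associated groups than in germfree, by 1.74 ± 0.47 (adjusted p = 0.0173), while in conventional samples it was -1.31 ± 0.53 relative to germfree (adjusted p = 0.0696). That difference was called in the permutation test per assay (adjusted p = 0.0286) and, with CEC replicate 7 and Nissle replicate 6 left out, in limma (-1.36 ± 0.35, adjusted p = 0.00239). With CEC alone the assay was 1.47 above germfree (adjusted p = 0.0873) with all samples and 1.95 (adjusted p = 0.000363) with those left out.

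Mm00470560_m1, 1 of the 2 assays that rose in all 3 colonised groups, was 1.24 log2 units higher in conventional than in mono-associated samples, a difference that did not pass the test (adjusted p = 0.169; 95% confidence interval -0.03 to 2.50). Of the 56 assays called between conventional and germfree, 28 were also called against the mono-associated mean in the same direction and 28 were not. In 44 of the 56 the mono-associated mean lay on the same side of germfree. In 100 simulations of unchanged groups the 56 assays with the smallest p had a mean of 47.3 on the same side, and 75 of the 100 had at least 44. Those assays were picked for chance values in the shared germfree samples. The simulations therefore cannot judge assays that truly changed, and no conclusion is drawn from the 44. Across the 146 assays measured in all samples, the covariance of the conventional and mono-associated fold changes against germfree was 0.276. Simulations of unchanged groups gave at most 0.142. Their r was 0.683, against a mean of 0.519 and at most 0.865 in the simulations. The fold changes had the same sign in 65.8% of assays, against a mean of 67.6% in the simulations. Without CEC replicate 7 and Nissle replicate 6 the covariance was 0.238, against at most 0.0987. The r was then 0.523, below the simulated mean of 0.549. Only the covariance therefore exceeded what shared germfree samples gave.

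Without CEC replicate 7 and Nissle replicate 6, 71 assays differed between conventional and mono-associated samples, 30 higher and 41 lower. The split moved with the scaling, to 24 higher and 13 lower with the median of the 146 assays, 28 and 13 with the 20 steadiest, 20 and 16 with raw Ct and 19 and 16 under quantile normalization. Under all 5 scalings 15 assays were higher and 9 lower, and without CEC replicate 7 and Nissle replicate 6 the numbers were 23 and 26.

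**Figure D3:**
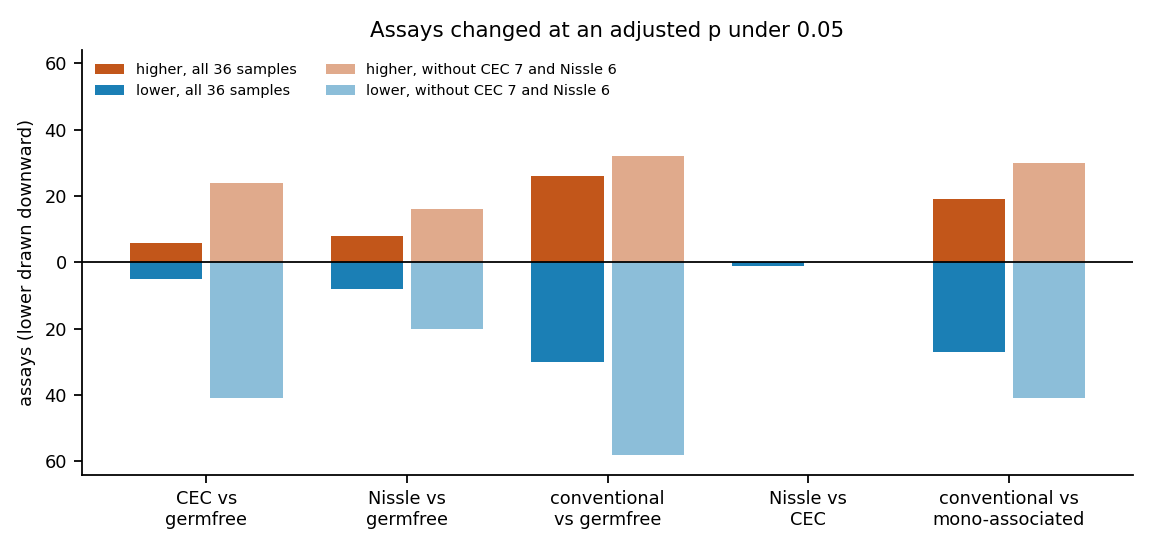
Bars give the number of assays higher (upward) and lower (downward) at an adjusted p under 0.05 in each comparison, with all 36 samples (dark) and without CEC replicate 7 and Nissle replicate 6 (light). Conventional against germfree had 56 and 90 calls, and Nissle against CEC had 1 and 0.

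Assays that amplified too rarely to be tested on their level were compared by detection. Of the 6 such assays with any Ct, 0 differed in any of the 5 comparisons (Fisher's exact test, adjusted). The only unadjusted p under 0.05 was 0.0498, for Mm01288386_m1, which was measured in 8 of 9 conventional and 3 of 9 germfree samples.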

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

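The tests of exchanged labels, failed wells, template input for Mm00470560_m1, its company among other assays and the undetermined wells of Nissle replicate 6 were chosen after the results were seen. The other explanations tested here address patterns that were themselves picked from these data. Samples were compared within each group on the assays measured, the mean Ct, the median absolute deviation and the level of each named assay, in 60 sets of values. Chance would mark about 3 of these, and 8 stood out, of which 5 were CEC replicate 7.

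CEC replicate 7 had a median absolute deviation of 1.05 log2 units from its group, against 0.14 to 0.303 in the other CEC samples. Its log2 relative level was -7.04 for Mm01208559_m1, where the others lay between -2.70 and -0.56. It was -5.88 for Mm00489956_g1 (others 0.13 to 0.88), -0.83 for Mm00441127_m1 (others 4.86 to 6.27) and -4.25 for Mm00452283_m1 (others -0.47 to 1.46).

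Low template input would bring losses in the weakest assays, but the Spearman rho across assays between its deviation and the Ct in the other CEC samples was 0.345 (bootstrap 95% interval 0.214 to 0.470), the opposite direction. That interval resamples the assays of 1 sample, which are not independent. The mean Ct of CEC replicate 7 was 21.8, the highest of all samples, as a lower input would give. Scaling removes such a shared shift, so the rho cannot judge it. A loss of wells is argued against by its 217 measured assays, where the other CEC samples had 198 to 221. A label exchanged within the series is argued against by its distance: the nearest group profile, conventional, was 0.946 log2 units away at the median assay, while the farthest of the other 35 samples was 0.477 from its own group. Germfree lay at 0.978, and its own group at 1.13. The limit set for an exchange was a distance under 1, which conventional and germfree met, so the criteria disagreed. Other explanations stay open, among them a sample from outside the series or a part of the mucosa with another make-up, since without gene names no markers could be tested. No biological explanation was tested.

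CEC replicate 6 was measured for 198 assays, where the others of its group had 215 to 221, and Nissle replicate 6 for 175, where the others had 215 to 219. The assays undetermined in Nissle replicate 6 were not weak ones: their median Ct in the other 8 Nissle samples was 21.8, and 40 of the 49 were measured in all of those. In the table's order, 47 of them stood in the first 112 assays and 2 in the last 112 (Fisher's exact test, p = 1.44e-14), and in CEC replicate 6 the numbers were 25 and 1. Neighbouring wells that failed together are a candidate explanation, but no source states that the table follows the order on the card. No biological explanation was tested.

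Germfree replicate 32 had a log2 relative level of 1.43 for Mm00489956_g1, where the other germfree samples lay between 0.46 and 0.81.

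In 4 of the named assays the mono-associated mean and the conventional group lay on opposite sides of germfree and differed from each other in limma. For Mm01208559_m1 the conventional minus mono-associated difference was -3.05, from 1.74 and -1.31 relative to germfree. It was 4.06 for Mm00472168_m1 (-0.54 and 3.52), 1.09 for Mm01288989_m1 (-0.21 and 0.88) and -1.80 for Mm00452283_m1 (0.13 and -1.67). For Mm01288989_m1 the strains lay on different sides of germfree, at 0.68 with CEC and -1.10 with Nissle. So they did for Mm00452283_m1, at -0.18 and 0.44, but without CEC replicate 7 and Nissle replicate 6 both lay above germfree, at 0.30 and 0.70. With all samples the mono-associated mean itself differed from germfree only for Mm01208559_m1, and with those samples left out for Mm00472168_m1 as well (-0.68, limma adjusted p = 0.0410).

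In Mm00470560_m1 the mean absolute deviation of the mono-associated samples from their group median was 6.34 times that of the germfree and conventional samples (permutation test, adjusted p = 0.0151 over 216 assays), and 0 of the other assays passed that test. That count was first taken as the test of noise in a single assay and would have left noise open; a test of companions, chosen afterwards, replaced it. Differences in template input could not produce it, since the range of the mean Ct was 0.129 of the assay's range, and without CEC replicates 6 and 7 and Nissle replicate 6 the ratio was 5.86. Noise in the wells of a single assay is argued against by a companion: across the 9 Nissle samples the closest of 167 other assays had an r of 0.98 (exact permutation p of the best of all = 0.000733). That companion, Mm01326247_m1, had a spread ratio of 4.65 without passing (permutation test, adjusted p = 0.0864). The wide spread was therefore not shown to be confined to Mm00470560_m1. Anything that moves several assays of a sample together, biological or technical, stays open. A biological difference in how far single samples responded to a strain is a hypothesis formed on these data, and it was not tested.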

How the results depend on the processing

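The repeats without CEC replicate 7 and Nissle replicate 6 and the scalings to the median or to the 20 steadiest assays were chosen after seeing the data, and the cause of each change was not tested unless stated. The counts for conventional against germfree (56) and against the mono-associated mean (46) stayed within 1.5 times except with sample quality weights, 94 and 95, and without the 2 doubted samples, 90 and 71. For CEC against germfree (11) the count was 27 under quantile normalization, 18 with Ct above 28 missing, 66 with sample weights, 65 without the doubted samples and 57 with these left out and the scaling kept to the original 146 assays. For Nissle against germfree (16) it was 10 under quantile normalization, 5 with raw Ct, 7 with undetermined wells filled in, 52 with sample weights, 36 without the doubted samples and 37 in that same scaling. The 1 call between Nissle and CEC became 0 under quantile normalization, filled-in wells, Ct above 28 missing, complete assays only and without the doubted samples (not tested in the last 3), and with the replicate block. The permutation test also gave 0, but could not have passed Mm01288989_m1 alone with 5 samples a side (smallest exact p = 0.00794). At an unadjusted p under 0.05 these alternatives gave between 8 and 17 assays. The correlation of the responses to the strains was 0.874 without the doubted samples, and scaling to the median leaves it at 0.79 by construction.

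Leaving out 1 sample at a time, the count for CEC against germfree ranged from 2 (without CEC replicate 9) to 56 (without CEC replicate 7), and was 7 without germfree replicate 10 and 6 without germfree replicate 22 or 31. For Nissle against germfree it ranged from 6 (without germfree replicate 31) to 35 (without CEC replicate 7), with 9 without Nissle replicate 1 or 4 and 10 without Nissle replicate 2 or 3. For Nissle against CEC it ranged from 0 to 2: 2 without Nissle replicate 4, and 0 without CEC replicate 1, 3, 4, 7 or 9 or Nissle replicate 1, 2, 7, 8 or 9. For conventional samples it ranged from 47 to 72 against germfree and from 42 to 66 against the mono-associated mean, highest without CEC replicate 7. Of the named assays' values with 1 sample left out, 571 kept their direction and side of the threshold and 21 kept their direction only. Under the other alternatives 209 kept both, 20 kept their direction only and 1 reversed: Mm01288989_m1 with Nissle against germfree, 0.0323 under quantile normalization. Neither tally counts cases in which an assay was no longer tested. Mm01288989_m1 was such a case without any 1 of its CEC or Nissle samples with a value.

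The replicate number did not pair the samples, as same-numbered samples of different groups correlated between -0.302 and 0.327. Of 8 Nissle samples, 0 correlated best with the CEC sample of their number. Of 8 conventional samples, 1 did so with the CEC sample and 2 with the Nissle sample of their number. With the replicate number as a block, conventional against mono-associated had 42 calls. Germfree shares only 1 number with the other groups, so no block was fitted there. The median log2 fold change of all assays in conventional against germfree was -0.08 with the mean scaling and 0.12 with the 20 steadiest assays. The single reference gene scaling and the gene lists were not run, as no assay could be named, and the planned mean of all complete assays became the scaling used. Detection differences stayed at 0 calls of 13 with Ct above 28 missing.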

Other observations

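The test of the company of Mm00470560_m1 was chosen after its spread was seen. Across the 9 Nissle samples 4 of 167 assays followed it at an adjusted p under 0.05 (exact permutation test), all 4 positively. The closest had a Pearson r of 0.98 (p = 1.93e-05, adjusted p = 0.00161) and a Spearman rho of 0.983 (p = 4.96e-05). Without the 2 samples farthest from the median of Mm00470560_m1 its r was 0.983. Since the assays are not paired with genes, it is open whether some of them measure the same transcript. The CEC samples fell into separate sets in this assay, so no correlation was computed there.

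The mean of the mono-associated groups differed from germfree in 30 assays, 17 higher and 13 lower, a comparison added after seeing the data. Under all 5 scalings 12 of the 30 were called, 6 higher and 6 lower. Without CEC replicate 7 and Nissle replicate 6 there were 68, 29 higher and 39 lower, of which 40 were called under all 5 scalings, 23 higher and 17 lower. In 4 assays the mono-associated mean differed from germfree and conventional samples differed from the mono-associated mean in the opposite direction, with no call between conventional and germfree.

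Other assignments of the same samples to groups of the same sizes were fitted in the same way, 100 per comparison with the real one included. For conventional against germfree 1 of 100, the real one, gave as many as 56 calls, and the highest other gave 11. For conventional against the mono-associated mean it was 1 of 100 for 46 calls, with 19 as the highest other, and for Nissle against germfree 1 of 100 for 16 calls, with 4. For CEC against germfree 3 of 100 gave as many as 11 calls, and the highest other gave 21. The counts that only the real assignment reached were rare under chance assignment of these samples, at a share under 0.05. Whether a sample is a mouse or a pool is open, so chance differences between mice are not excluded. For Nissle against germfree the count fell to 6 without germfree replicate 31, and the assignments were not repeated there. For CEC against germfree 100 assignments are too few to place the share firmly under 0.05, and that count fell to 2 without CEC replicate 9. For Nissle against CEC 13 of 100 gave at least 1 call, up to 4, so chance cannot be excluded there.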
